A study of Phytophthora nicotianae
Citrus sinensis x Citrus trifoliata and Citrus sinensis x Citrus trifoliata with 7 samples.

How the data were processed

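RNA was sequenced from roots of Carrizo citrange seedlings, a hybrid citrus rootstock of sweet orange and trifoliate orange, after inoculation with zoospores of Phytophthora parasitica (also named Phytophthora nicotianae), an oomycete that causes root rot, or after mock treatment with sterile water. Per the labels' protocols, seedlings were 60 days old and each treatment used 50 ml of liquid. The series lists 7 samples. The table analysed here holds 6 libraries, which are 2 infected and 1 noninfected library at 24 h and the same at 48 h. The 0 h sample, labelled as citrus with the pathogen, was not analysed here, so the comparisons planned against it were not made. Nothing in the labels says whether the replicate libraries came from separate plants, so the p-values measure only the spread between these libraries, which may be technical.

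The deposited values are expected counts per assembled transcript, not normalized, per the row names and the values themselves: 40.7% of the values are not whole numbers (tolerance 1e-09). Rows are transcripts of a de novo assembly made with Trinity, per the file headers and row names, which also give the assembly gene (a cluster of transcripts) that each transcript belongs to. The submitters' processing notes name FastQC 0.11.5, Trim Galore 0.4.3, Bowtie2, TopHat, RSEM and edgeR, without saying which step each served. RSEM divides reads that match several transcripts among them by a statistical estimate, so the count of 1 transcript of a gene can move to another without a change in the gene's total. The genome build, the assembly settings and any filter on transcripts are not given in the sources used here. The row names are assembly identifiers that the file does not pair with gene names, sequences or coordinates: 0 identifiers could be matched to a gene name. The gene lists fixed beforehand therefore could not be tested, the identifiers do not tell citrus from Phytophthora transcripts, and at most 2 transcripts that rose and 2 that fell are named per comparison.

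Library columns were assigned to samples by the run name in the sample titles. Expected counts were rounded to whole numbers. Transcripts with at least 1 CPM (counts relative to the library total) in at least 2 libraries were kept, which left 28280 of 40943 transcripts and at least 99.7% of each library's counts. Libraries were scaled by TMM, and edgeR 4.0.16 (R 4.3.3) was fitted with 1 mean per group over the 6 libraries, followed by its quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. Each group mean of the noninfected roots rests on 1 library, so the spread comes from the infected replicates alone (2 residual degrees of freedom, moderated by 3.36 prior degrees of freedom) and the noninfected libraries were assumed to vary like them. The biological coefficient of variation was 16.5%. The comparisons were infected against noninfected at 24 h, the same at 48 h, the mean of both, infected at 48 h against infected at 24 h, and the difference between the 48 h and 24 h effects. The planned design assumed 7 libraries in the fit; a lone 0 h library adds nothing to the spread.

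The standard error of a log2 fold change is the fold change divided by the square root of its F statistic. CPM values are TMM-scaled and are given as mean ± SD. Where a group was at 0 in all its libraries, the fold is a lower bound against a floor of 3 counts per library, and such transcripts also entered medians and counts of fold sizes at that bound. Intervals on ratios of counts and on shares of counts are exact 95% binomial intervals; these and the floor cover counting error only. Named transcripts are the 2 largest rises and the 2 largest falls on the fitted scale among those past the threshold, with a mean of at least 5 CPM in the higher group and with every library of 1 group beyond every library of the other at the same time. That rule, the comparisons and the alternatives were chosen before the data were examined. The comparisons of library pairs, the overlaps, the shares of counts, the sets of transcripts at 0, the checks on the gene-level counts and the alternatives that change the noninfected libraries or leave out the most abundant transcript were added afterwards.

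Pairs of libraries were compared over assembly genes with at least 50 counts in the pair, leaving out the gene of the most abundant transcript, by the squared deviation from a constant ratio, divided by the value that counting alone gives, and by exact binomial tests with Benjamini-Hochberg adjustment. Such a test compares libraries, not conditions. Alternatives were DESeq2 size factors and upper-quartile factors in edgeR, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter, a filter at 5 CPM, a minimum log2 fold change of 1, an additive model, a replicate block, each infected library left out, and counts summed per assembly gene. The pipeline was tested on simulated counts in which known transcripts were changed by 2-fold or 4-fold. For the mean of both times it recovered 73.1% of 4-fold and 34.4% of 2-fold changes, with 10 calls among unchanged transcripts of 27213 simulated. For 24 h alone it recovered 34.7% of 4-fold and 1.04% of 2-fold changes, and for 48 h alone 54.6% and 11.5%. For the mean of both times, the 10 false calls stood beside 68 recovered 4-fold and 33 recovered 2-fold changes. For infected roots at 48 h against 24 h, 11 false calls stood beside 48 and 19. For the difference of effects, 4 stood beside 17 and 0. In each of these comparisons, from a single simulation, the false part of the calls lay above the threshold of 0.05. In the 24 h simulation 98 transcripts were changed by 4-fold and 96 by 2-fold among 27233, a far smaller share than was called in the data. The adjusted threshold was therefore stricter in the simulations, so these recoveries do not give the power in the data.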

Results

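The transcriptional response of Carrizo citrange roots to Phytophthora parasitica was followed at 24 h and 48 h after inoculation in 4 infected and 2 noninfected root libraries. Library totals ranged from 5700819 to 6675146 expected counts, and between 30655 and 32528 of the 40943 assembled transcripts were detected in a library. At these depths a count of 0 in 1 library allowed a level of up to 0.436 to 0.536 CPM on the TMM scale, depending on the library. The most abundant transcript, TRINITY_DN5100_c4_g1_i1, singled out after its values were seen, took a share of the counts that differed between libraries. It held 4.34% of the counts in the noninfected library at 24 h (95% interval 4.32 to 4.35%) and 21.3% in the noninfected library at 48 h (21.3 to 21.4%). In infected roots its share was 11.7% and 3.72% in the 2 libraries at 24 h, and 10.9% and 15.2% at 48 h.

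The first question was which transcripts differed between infected and noninfected roots after 24 h. Of the 28280 transcripts tested, 5547 were higher and 3935 were lower in infected roots (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), together 33.5% of those tested. Among called transcripts, which favour large changes, the median rise was 4.01-fold and the median fall 3.22-fold, and 2777 rises and 1565 falls reached 4-fold. Summed per assembly gene, 4494 genes were higher and 4218 were lower among the 16695 tested. Transcript TRINITY_DN17745_c0_g1_i1, the only transcript of its gene, was at 0 in the noninfected library and at 329 ± 23.9 CPM (SD, n = 2) in infected roots, at least 755-fold higher (adjusted p = 0.000712, edgeR). It had 6 counts in the noninfected library of 48 h, and with that library as the control its fitted log2 fold change was 8.36. TRINITY_DN15257_c0_g1_i1 went from 0 to 403 ± 19.7 CPM (SD, n = 2), at least 925-fold higher (adjusted p = 0.000578, edgeR), although the sum of its gene's 2 transcripts rose by only 0.71 ± 0.15 on the log2 scale (SE). This transcript had 13 counts in the noninfected library of 48 h, and with that library as the control its fitted log2 fold change was 7.55, so both bounds rest on the 0 of 1 library. TRINITY_DN23786_c0_g1_i1 fell from 136 CPM to 0 in both infected libraries, at least 295.5-fold lower, and TRINITY_DN39802_c0_g1_i1 fell from 52.2 CPM to 0 in both, at least 113-fold lower (adjusted p = 0.000663 and 0.00204, edgeR). Each of these 2 was the only transcript of its gene. Without infected replicate 1 at 24 h the count of calls was 4482, and without infected replicate 2 it was 3588. Because the identifiers do not tell the organisms apart, transcripts called higher here and in all other comparisons with noninfected roots can include those of the pathogen. The calls between infected roots of 48 h and 24 h, in either direction, and those for the difference of effects can include them too.

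At 48 h the same comparison was made. In infected roots 6568 transcripts were higher and 5598 lower than in the noninfected library (edgeR, same threshold), which is 43.0% of those tested. The median called rise was 3.83-fold and the median called fall 4.11-fold, and 3181 rises and 2849 falls reached 4-fold. Summed per assembly gene, 5096 genes were higher and 4966 lower. TRINITY_DN23214_c3_g3_i1 was at 0 in the noninfected library and at 804 ± 56.4 CPM (SD, n = 2) in infected roots, at least 1637-fold higher (adjusted p = 0.000305, edgeR). The gene it belongs to has 4 transcripts, whose sum rose by 9.41 ± 0.30 on the log2 scale (SE), from 5.77 CPM to 3819 and 4065 CPM. TRINITY_DN16870_c1_g1_i2 was at 0 and then at 272 ± 33.6 CPM (SD, n = 2), at least 553.5-fold higher (adjusted p = 0.000447, edgeR), while its gene's sum rose by 1.23 ± 0.18 (log2, SE). TRINITY_DN13743_c0_g1_i4 fell from 159.8 CPM to 0 in both libraries, at least 299-fold lower, and the sum over its gene fell by 5.46 ± 0.28 (log2, SE). TRINITY_DN22801_c2_g2_i4 fell from 219 CPM to 0, at least 410.3-fold lower, with a fall of 1.40 ± 0.16 (log2, SE) for its gene's sum.

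**Figure D1:**
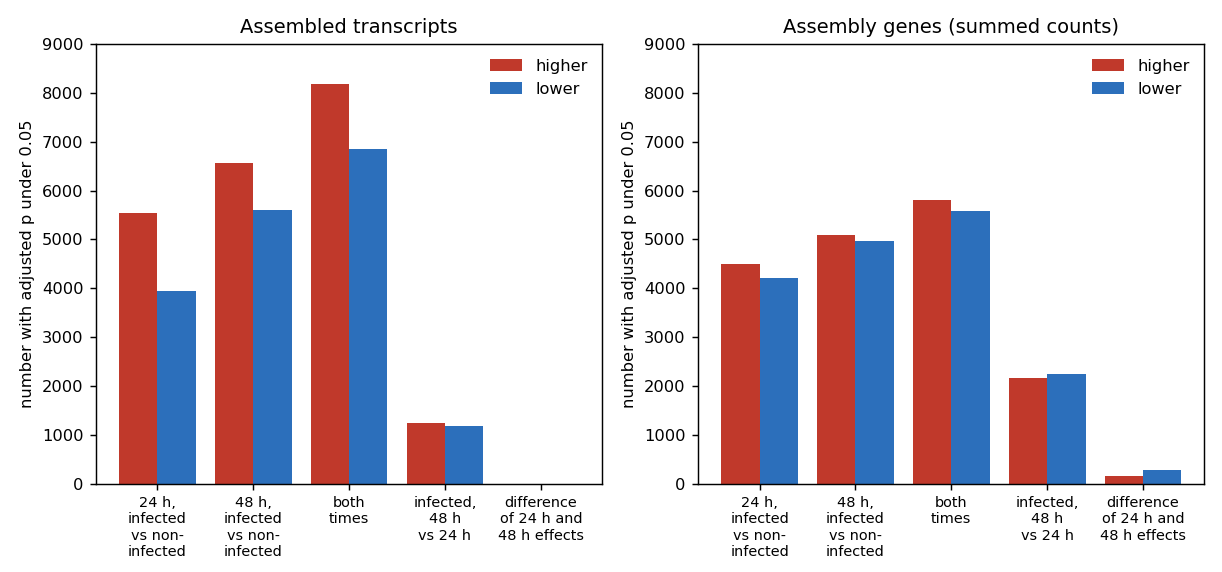
Number of assembled transcripts (left) and assembly genes (right) with an adjusted p under 0.05 in each comparison; red bars are higher and blue bars lower in the group named first, and in the last comparison red means an effect more positive at 48 h. The calls number 9482 transcripts and 8712 genes at 24 h and 12166 and 10062 at 48 h. Which time had more transcript calls depended on the infected library left out. The difference between the effects at the 2 times gives 0 transcripts and 432 genes.

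Most transcripts that were called at 24 h were called in the same direction at 48 h. Of the 5547 transcripts higher at 24 h, 4556 (82.1%) were also higher at 48 h, where independent lists would share 1288. Of the 3935 lower at 24 h, 3367 (85.6%) were also lower at 48 h, where independent lists would share 779. Only 33 transcripts were called in opposite directions at the 2 times, against 2012 for independent lists. A further 2000 transcripts were higher and 2210 lower at 48 h without being called at 24 h, and 970 higher and 556 lower transcripts at 24 h were not called at 48 h; these lists do not show that the effects differed between times, which is tested separately. The correlation of the fitted log2 fold changes at the 2 times was 0.793 across transcripts, which are not independent replicates. It was 0.846 for differences of mean log2 CPM with a prior count of 2, the measure used in the simulations. If both noninfected libraries came from 1 RNA sample, chance alone would give a correlation of 0.444 (mean of 20 simulations without any effect); the covariance was 2.81 against a simulated 0.137. With 1 noninfected library per time the controls cannot be split, so part of the agreement beyond independent lists may come from them.

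**Figure D2:**
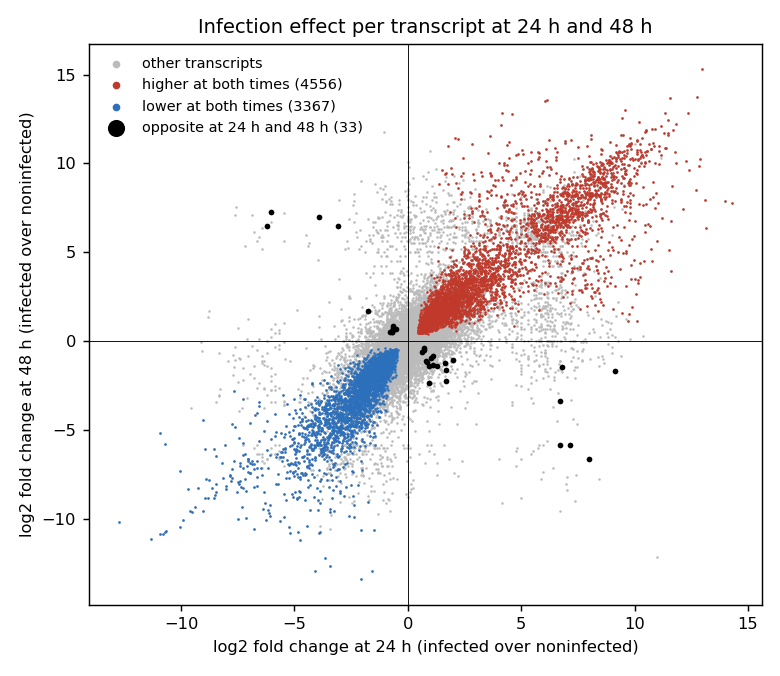
Fitted log2 fold change of infected over noninfected roots at 24 h (x axis) and at 48 h (y axis), 1 point per tested transcript; red points were called higher at both times (4556), blue points lower at both (3367), black points in opposite directions (33), and grey points are all others. Most coloured points lie in the upper right and lower left quadrants; the points far from the origin include transcripts at 0 in 1 group, whose fitted fold depends on the prior count.

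The transcripts that moved at both times held a different part of the counts in infected and noninfected libraries. With the most abundant transcript left out of the total, the 4556 risen transcripts held 13.2% of the counts in each noninfected library, 36.8 ± 1.42% (SD, n = 2) in infected roots at 24 h and 45.5 ± 0.88% at 48 h. The 3367 fallen transcripts went from 29.6% and 29.1% in the noninfected libraries at 24 h and 48 h to 8.78 ± 0.59% and 5.52 ± 0.57% in infected roots (SD, n = 2). Both sets were chosen on these same libraries, so these shares describe them and are not a test.

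Averaged over both times, 8178 transcripts were higher and 6843 lower in infected roots (edgeR, adjusted p under 0.05), 53.1% of those tested, with median called changes of 3.11-fold up and 2.93-fold down. Summed per assembly gene, 5798 genes were higher and 5571 lower, 68.1% of 16695. A set of 802 transcripts, defined after the values were seen, was at 0 in both noninfected libraries and had at least 5 counts in each of the 4 infected libraries. All 802 passed the test, but they were picked on the same libraries, so this adds no support. The opposite pattern was shown by 73 transcripts. It requires 0 in 4 libraries rather than 2, so the sizes of the 2 sets are not directly comparable. The 2 largest rises were again TRINITY_DN23214_c3_g3_i1 and TRINITY_DN16870_c1_g1_i2, at least 1042-fold and at least 442-fold higher (adjusted p = 7.21e-05 and 0.000104, edgeR). The sum over the gene of the former rose by 8.78 ± 0.21 and that of the latter by 0.82 ± 0.12 (log2, SE). TRINITY_DN39802_c0_g1_i1 was at 48.6 ± 5.06 CPM in the noninfected libraries (SD, n = 2) and at 0 in all 4 infected libraries, at least 97.8-fold lower (adjusted p = 0.000435, edgeR). TRINITY_DN23786_c0_g1_i1 had 1717 counts over the noninfected libraries and 1 count over the infected ones, a ratio of 3209 (exact 95% interval 575 to 126800; adjusted p = 9.55e-05, edgeR).

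In noninfected roots, 48 h and 24 h were compared as values only, since 1 library at each time gives no spread of its own; no test of time was run for them. The 2 libraries differed by little more than the sampling noise, with a squared deviation per assembly gene of 1.17 times that of counting alone, against 2.17 and 3.28 for the infected replicate pairs at 24 h and 48 h. Exact binomial tests, which compare libraries and not conditions, found a difference between the 2 noninfected libraries in 58 of 12976 assembly genes (0.447%, the gene of the most abundant transcript left out here and in the other pairs), in 1313 of 12930 (10.2%) between the infected replicates at 24 h, and in 2197 of 12005 (18.3%) between those at 48 h. Pairs of an infected and a noninfected library ranged from 33.95 to 64.4 times the counting noise. Because the noninfected libraries were so close, they were also counted as 1 sample, which gave 6538 higher and 5506 lower transcripts over both times (edgeR).

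**Figure D3:**
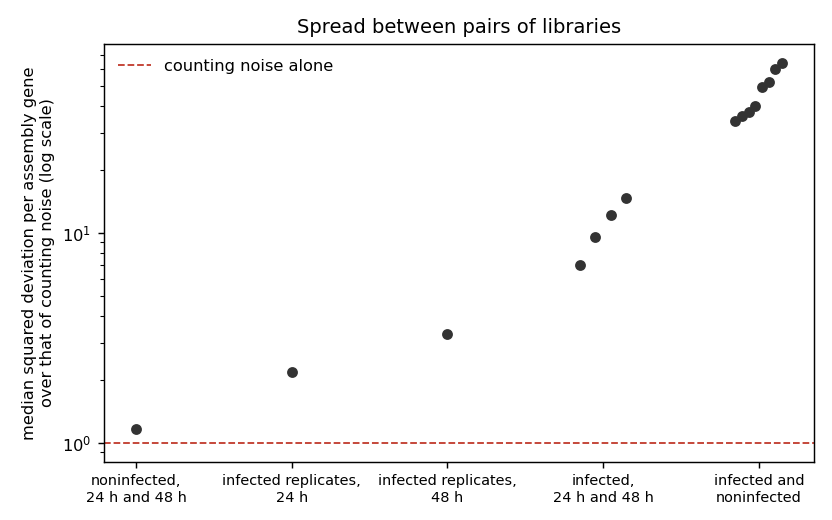
Median squared deviation of assembly-gene counts between 2 libraries, divided by that of counting noise (y axis, log scale), for the 15 pairs of libraries grouped by kind (x axis), 1 point per pair; the dashed line marks counting noise alone. The noninfected pair lies at 1.17, below the infected replicate pairs at 2.17 and 3.28, and the pairs of infected with noninfected libraries lie between 33.95 and 64.4.

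The next question was how infected roots changed from 24 h to 48 h. Between the 2 infected groups 1237 transcripts rose and 1183 fell (edgeR, adjusted p under 0.05), with median called changes of 2.30-fold up and 2.88-fold down; per assembly gene, 2163 rose and 2244 fell. Of the 1237 that rose, 754 were already higher than in noninfected roots at 24 h and 82 were lower, where independent lists would give 243 and 172. Of the 1183 that fell, 500 were already lower at 24 h and 283 were higher, against 165 and 232. Because the infected 24 h libraries enter both comparisons with opposite signs, chance alone makes them oppose each other. The correlation of the 24 h effect with the later change was 0.177 across transcripts and -0.406 in simulations without effects. Among the 283 transcripts that were higher at 24 h and then fell, 113 were still called higher and 152 were no longer called at 48 h.

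TRINITY_DN20473_c0_g1_i4 was at 0 in both infected libraries at 24 h and at 21.5 ± 8.45 CPM (SD, n = 2) at 48 h, at least 46.7-fold higher (adjusted p = 0.016, edgeR), and its gene's sum rose by 1.33 ± 0.16 (log2, SE). TRINITY_DN16932_c0_g1_i3 was at 0 and then at 12.35 ± 7.61 CPM, at least 26.8-fold higher (adjusted p = 0.0294, edgeR), but had 60 and 23 counts in the noninfected libraries, and its gene's sum rose by 0.86 ± 0.16. TRINITY_DN22801_c2_g2_i4 fell from 58.0 ± 13.2 CPM to 0, at least 109-fold lower (adjusted p = 0.0105, edgeR), and TRINITY_DN21757_c4_g1_i2 fell from 35.2 ± 2.05 CPM to 0, at least 65.9-fold lower (adjusted p = 0.00531, edgeR); the sum over the gene of the former fell by 0.74 ± 0.14 and that of the latter fell by 1.28 ± 0.13 (log2, SE). All 4 missed the threshold without either infected library of 24 h (adjusted p from 0.121 to 0.21, edgeR). TRINITY_DN20473_c0_g1_i4 also missed it with DESeq2 (adjusted p = 0.178), TRINITY_DN16932_c0_g1_i3 with limma-voom (adjusted p = 0.0764) and with no low-count filter (adjusted p = 0.0738, edgeR). Without infected replicate 1 at 48 h, TRINITY_DN16932_c0_g1_i3 and TRINITY_DN22801_c2_g2_i4 missed it (adjusted p = 0.0758 and 0.0513, edgeR). The number of transcripts called between the 2 infected times was 0 without either infected library of 24 h, 63 without infected replicate 1 at 48 h and 1312 without infected replicate 2 at 48 h, and 643 with no low-count filter. The count of assembly genes was 1155 without infected replicate 1 at 24 h, 2208 without replicate 2 at 24 h, 1931 without replicate 1 at 48 h and 3933 without replicate 2 at 48 h.

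Whether the effect of infection differed between 24 h and 48 h was tested as the difference of the 2 effects. No transcript passed (edgeR, 0 of 28280, with 4051 at an unadjusted p under 0.05), and none passed with limma-voom, whereas DESeq2 called 853 transcripts, and edgeR called 22 with a filter at 5 CPM. On simulated counts with few transcripts changed, this test recovered 0% of 2-fold and 17.7% of 4-fold differences. It also made 4 calls among unchanged transcripts, beside 17 recovered ones. Summed per assembly gene, 432 of 16695 genes passed in edgeR, with an effect that was more positive at 48 h in 147 and more negative in 285. By the fitted effects, whether or not each passed the test at its own time, 303 of the 432 had the same direction at both times and a larger size at 48 h, as a rise in 98 genes and a fall in 205. In 24 the size was smaller at 48 h, and in 105 the fitted effects had opposite signs at the 2 times. The count of 432 became 0 without infected replicate 1 at 24 h, 16 without replicate 2 at 24 h, 0 without replicate 1 at 48 h and 387 without replicate 2 at 48 h, and 731 with DESeq2 size factors in edgeR.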

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

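With counts summed per assembly gene, 432 of 16695 genes passed the test of the difference between the 24 h and 48 h effects (edgeR quasi-likelihood test, adjusted p under 0.05). In the main fit per transcript, 0 of 28280 passed the same test. The gene-level result met the criterion for a closer look because 2 time points differed under the same contrast. The median absolute difference between the 2 effects was 1.84 on the log2 scale. All 432 genes were also called between the infected roots of 48 h and 24 h. The difference of effects contains that comparison, on the same infected libraries, so the overlap is not separate support. Of them, 299 were called against noninfected roots at both times, 101 at 48 h only and 32 at 24 h only. The checks that follow were chosen after this result was seen. The count was 0 without infected replicate 1 of 24 h, 16 without infected replicate 2 of 24 h, 0 without infected replicate 1 of 48 h and 387 without infected replicate 2 of 48 h. It was 731 with DESeq2 size factors in edgeR.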

How the results depend on the processing

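Across the alternatives, 64 of 76 counts of calls stayed within 1.5 times the reported count. This tally includes counts for the difference of effects that stayed at 0, which a minimum fold change could not raise. It also sets counts of assembly genes against counts of transcripts. At 24 h, 8712 genes (52.2% of those tested) thus count as unchanged from 9482 transcripts (33.5%). Of the named transcripts, 208 of 224 values kept their direction and their side of the threshold. The other 16 values, all for infected roots of 48 h against 24 h, kept their direction and missed the threshold. Named transcripts were picked for the largest folds and had 1 group at or near 0, so their direction could hardly change. The minimum log2 fold change of 1 uses the main fit and could not move them. Transcripts removed by the low-count filter of an alternative have no value there. TRINITY_DN23786_c0_g1_i1 and TRINITY_DN39802_c0_g1_i1 over both times were thus not checked with noninfected libraries combined or left out. TRINITY_DN20473_c0_g1_i4 was not checked without either infected library of 48 h. The alternatives chosen after seeing the data were the exchanged or combined noninfected libraries, each noninfected library left out and the most abundant transcript left out; these moved no count by over 1.5 times. For infected against noninfected roots at 24 h, the counts without 1 infected library ranged from 3588 to 10152 transcripts, and at 48 h no alternative moved the count of 12166 by over 1.5 times. For infected roots at 48 h against 24 h, the 2420 calls became 643 with no low-count filter, 4407 assembly genes when counts were summed per gene, and between 0 and 1312 without 1 infected library. The difference between the 48 h and 24 h effects, with 0 calls, became 22 with a filter at 5 CPM, 853 with DESeq2 and 432 with counts summed per assembly gene. The cause of these shifts was not tested, except that leaving out a library leaves 1 residual degree of freedom. Only the infected libraries carry replicate numbers, and their deviations at the 2 times did not go together (r = -0.029 across transcripts), so the numbers are not taken to pair the samples. With the replicate block, which also leaves 1 residual degree of freedom, the 48 h against 24 h count was 55, and the other counts stayed within 1.5 times. In that comparison TRINITY_DN20473_c0_g1_i4, TRINITY_DN16932_c0_g1_i3 and TRINITY_DN21757_c4_g1_i2 missed the threshold with the block (adjusted p = 0.0599, 0.0603 and 0.0548, edgeR). Summed per assembly gene, the block gave 4844 calls for 48 h against 24 h and 1307 for the difference of effects. Another scaling moved the share of higher calls by less than 10 percentage points, and the median of all transcripts by less than 0.1 on the log2 scale. All scalings compared place the bulk of transcripts near no change, so little movement could be seen. With 53.1% of transcripts called over both times, that shared assumption was not tested. The balance of higher and lower calls may depend on it. The alternatives that use the 0 h library or separate the organisms were not run. Depth limits the rarest transcripts: a count of 0 in 1 library allows up to 0.536 CPM.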

Other observations

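The comparison over both times and the counts per assembly gene were planned; the other tests in this part were chosen after the results they concern had been seen. Among transcripts past the threshold over both times, the 2 largest rises and the 2 largest falls in mean CPM were in abundant transcripts that are each the only transcript of their gene. The largest fall was in a transcript that stood at 7554 and 7260 CPM in the noninfected libraries, at 786.5 ± 158.5 CPM in infected roots at 24 h and at 225 ± 63.8 CPM at 48 h (SD, n = 2), a fall of 17.6-fold averaged over both times (adjusted p = 0.000128, edgeR). Another fell from 4248 and 4021 CPM to 399.8 ± 8.38 and 245 ± 64.5 CPM, 13.2-fold (adjusted p = 1e-04, edgeR). A transcript that rose went from 337 CPM in each noninfected library to 3932 ± 289 CPM at 24 h and 6796 ± 962.5 CPM at 48 h, 15.4-fold (adjusted p = 8.37e-05, edgeR). The most abundant of the 4 was at 17990 and 23050 CPM in the noninfected libraries, at 22440 ± 288 CPM at 24 h and at 35220 ± 1404 CPM at 48 h, a rise of 1.38-fold averaged over both times (adjusted p = 0.00668, edgeR). Its noninfected level at 48 h lay above its infected mean at 24 h. The p-value takes no spread from the noninfected libraries, so it does not weigh the gap between them.

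Transcripts of the same assembly gene were called in opposite directions less often than random placement gives. Among 6012 assembly genes with at least 2 tested transcripts, 171 held both a transcript that was higher and a transcript that was lower at both times, where placing the calls on transcripts at random gave 604 (mean of 1000 permutations). At the level of assembly genes, 3748 genes were higher and 3654 lower at both times, against 1372 and 1255 for independent lists, and 43 went in opposite directions, against 2624.

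The noninfected libraries of 24 h and 48 h differed little beyond sampling noise, and these are the only controls analysed here. A single library deposited under both names is argued against by the most abundant transcript, whose share was 4.92 times as high in the 48 h library, with intervals far apart. Libraries made from one RNA sample or pool remain a candidate explanation: the squared deviation was 1.17 times that of counting alone (bootstrap 95% interval 1.12 to 1.21 over assembly genes), below the 2.17 of the closest infected replicates. Roots of separate noninfected seedlings that changed little between the times cannot be told apart from this with 1 library per time, since 58 differing genes have no second noninfected pair to be set against. If the controls were 1 sample, the spread between noninfected plants would be unmeasured, and the counts of calls could depend on that sample. There would then be no separate noninfected baseline for each time. A change with time alone could then not be told from a difference between the infection effects at 24 h and 48 h.

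The 802 transcripts at 0 in both noninfected libraries could have several sources. Estimated counts assigned to another listed transcript of the same assembly gene cannot apply to 310 of them, which are the only listed transcript of their gene. Whether a filter had removed other transcripts of these genes is not known. Reads shared with transcripts of other assembly genes were not examined. For 70 of the other 492 the gene had at most 3 counts over both noninfected libraries, which argues against that explanation for these 70. For the remaining 422 the gene did have counts there, so that explanation cannot be told apart from a real change of transcript. Transcripts of Phytophthora may be among the 802. With the most abundant transcript left out of the total, the set held 0.694 ± 0.011% of the counts in infected roots at 24 h and 0.963 ± 0.011% at 48 h (SD, n = 2), a share 1.39 times as high. However, 3452 risen transcripts with more than 3 noninfected counts also rose, by 1.22 times, so the test leaves pathogen and strongly induced citrus transcripts open. Of 4997 assembly genes with at least 1000 counts over the infected libraries, 9 were at 0 in both noninfected libraries and 35 had 1 to 10 counts.

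The share taken by TRINITY_DN5100_c4_g1_i1 differed 3.14 times between the infected replicates of 24 h and 1.40 times between those of 48 h. If an RNA class was removed to different extents in each library preparation, other genes should follow it. With its own gene left out, of the 34 assembly genes higher in the noninfected 48 h than 24 h library, 61.8% followed this transcript in both infected replicate pairs, against 27.3% of the other 12942 genes (Fisher's exact test, two-sided, p = 4.61e-05, with genes not independent), which is consistent with such a class. The 3.14 times between replicates of one time argues against time after treatment as the source of that part. For the difference between the times, with means of 6.58% at 24 h and 15.8% at 48 h, time after treatment remains open (exact permutation test, two-sided, p = 0.2, where 3 libraries against 3 cannot go below 0.1). By infection the means were 10.4% in infected and 12.8% in noninfected libraries (exact permutation test, two-sided, p = 0.8, where 4 libraries against 2 cannot go below 0.0667).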
